A study of Homo sapiens with 2 samples.

How the data were processed

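Gene expression was measured by RNA-seq on an Illumina HiSeq instrument in 2 libraries of UM-UC-3, an established human bladder cancer cell line. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with standard Illumina protocols. 1 library came from cells that had received a lentivirus with an empty vector and 1 from cells that had received a lentivirus with AP-2α cDNA, 48 h of infection and then puromycin at 1 µg/mL in each group. Groups were taken from the labels.

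The submitters' processing notes name TopHat2, Cufflinks and the genome build GRCh37, without versions or roles. The annotation release, the counting program, the strand setting and any filter are not given in the sources used here. Each library has a deposited file with 20837 genes, of which 20072 have Ensembl identifiers and 765 are loci that the authors named as new genes. Per the file headers, the authors deposited for each gene a raw count, which is a whole number and sums to a different total in each library. Per the file headers, the authors also deposited an FPKM, the fragments per kilobase of gene scaled to library size. The authors deposited as well a normalized score, which is the count times a factor of about 0.873 in the empty-vector library and 1.15 in the AP-2α library, made by a method that the file headers do not state. 4 columns of per-sample values in tables of the whole series were not used, because their names match neither sample's labels. The files used here have 0 genes on the mitochondrial chromosome.

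Symbols were looked up by Ensembl identifier, and 18838 of the identifiers had one. Coordinates are those in the authors' files. Transcript GC content was taken by identifier from GENCODE release 29, from the longest transcript of each gene, and was known for 92.7% of the measured genes. No coordinate of that release was used, since it belongs to another build.

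The main measure was the deposited count, scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, and the log2 ratio of scaled counts (CPM) of the AP-2α over the empty-vector library. Its 95% interval is the exact Clopper-Pearson interval on the split of the 2 counts. With 1 library per group there is no replicate error, so no p-value was computed, and intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules. A gene was measured when it had at least 20 counts over both libraries, and was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. A count of 0 would have been replaced by a floor of 3 counts, worth 0.147 CPM in the empty-vector library and 0.178 CPM in the AP-2α library; 0 called genes needed it.

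Before the data were examined, 29 gene lists were fixed. A list with at least 5 measured members was described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to stand apart below percentile 2.5 or above 97.5. The counting range of a percentile is the middle 95% of 100 draws of the members' counts. Such a percentile describes these 2 libraries and not the conditions. The genes named were the AP-2 family, the 12 called genes with the highest and the 12 with the lowest ratio, and the 2 highest and 2 lowest members of each list, ranked by the interval end nearest to 1. Unnamed loci, pseudogenes, antisense genes, XIST and Y-linked genes stayed outside this rule. Called list members outside the rule, loci without a symbol and 6 further lists were chosen after their values had been seen. Single values of some genes that the rule names are not reported here.

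The alternatives fixed before the data were examined were other scalings (total count, DESeq2 1.42.0 size factors, upper quartile, and the total without the 100 most abundant genes), other count minimums, folds and interval rules, the authors' FPKM, and other ways to summarise and match the lists. Alternatives chosen after seeing the data were a correction for GC content and gene length, the authors' normalized scaling, protein-coding genes alone, and the empty-vector library thinned to the AP-2α total. The correction was a cubic fit of the log2 ratio on GC content and log2 length with their product. It was fitted over 10638 genes with at least 100 counts, and explained 22.2% of the variance of the log2 ratio. It is the only form of correction that was tried, and it also removes any biological difference that follows GC content or length.

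The calling rule was tested on simulated data, with counts drawn for the 12944 measured genes from the means and depths of this comparison and 200 of them changed. With counting error alone it recovered 98 of 100 genes changed 3-fold and 98 of 100 changed 8-fold, and of 12744 unchanged genes it called 18 higher and 17 lower. With an assumed biological coefficient of variation of 20%, it called 191 unchanged genes higher and 193 lower, and with 30% it called 801 higher and 745 lower. The real variation between cultures is unknown here, so part or all of the called genes can differ for reasons other than the treatment. In the data 85 genes were called higher, fewer than the 191 with 20%. The 542 called lower were more than the 193 with 20% and fewer than the 745 with 30%. Simulated calls were near even between higher and lower at each setting, so none of the settings gave the imbalance in the data. Of 100 random lists of 25 measured genes, 4 stood apart. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.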

Results

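Gene expression was compared between UM-UC-3 human bladder cancer cells that carried an AP-2α cDNA and cells that carried an empty vector, to find genes whose expression differs when AP-2α is overexpressed. AP-2α is a DNA-binding transcription factor encoded by TFAP2A. There was 1 library per group and no replicates, so each difference is between these 2 libraries. The empty-vector library held 20405711 counts and the AP-2α library 16884987, and 16127 and 15484 genes had at least 1 count. The most abundant gene was GAPDH in both, with 1.19% of the counts in the empty-vector library and 1.23% in the AP-2α library, and the 10 most abundant genes took 6.29% and 6.16%.

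TFAP2A was 2.66-fold higher in the AP-2α library (95% counting interval 2.49 to 2.84), at 64.0 CPM with the empty vector and 170 CPM with AP-2α. The gene (ENSG00000137203) lies on chromosome 6 from 10393419 to 10419892, minus strand, GRCh37. It had 1327 and 2830 counts, so the line already expressed it without the cDNA. On the authors' FPKM scale the values were 27.2 and 105, a ratio of 3.86, larger than in counts. TFAP2C, the paralog that shares the AP-2 binding site, was 2.86-fold lower (1.20 to 7.84) on 25 and 7 counts. TFAP2E had 14 and 2 counts, below the minimum, and TFAP2B and TFAP2D had 0 in both libraries.

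Besides TFAP2A, the genes that stood highest with AP-2α included enzymes of the oxidative stress response and a G1/S cyclin. NQO1, a quinone reductase, was 2.69-fold higher (2.58 to 2.81), at 147 CPM with the empty vector and 396 CPM with AP-2α. HMOX1, the inducible heme oxygenase, was 2.34-fold higher (2.15 to 2.55). CCNE2, which encodes cyclin E2, was 2.49-fold higher (2.16 to 2.87), on 291 and 580 counts. GCKR, the glucokinase regulatory protein, had the highest ratio of the named genes, 6.30-fold (4.45 to 9.13), on 39 and 197 counts, and lies on chromosome 2 from 27719706 to 27746652. CST7, a cysteine protease inhibitor, was 5.86-fold higher (2.92 to 13.0) at only 10 and 47 counts. UPP1, a uridine phosphorylase, was 3.07-fold higher (2.74 to 3.44). PHLDA2, an imprinted gene, was 2.20-fold higher (2.08 to 2.31), SH3TC2 2.74-fold (2.10 to 3.60), and SAT1, which acetylates polyamines, 2.31-fold (2.12 to 2.51). After correction for GC content and length SAT1 was 1.86-fold higher and no longer met the 2-fold rule. The hair keratin KRT81 was 3.90-fold higher (2.18 to 7.33) and the keratin-associated gene KRTAP2-3 2.74-fold (2.33 to 3.22), both of them members of gene families whose near-identical copies can share reads, so their values are uncertain.

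Many of the genes that stood lowest with AP-2α were expressed at low levels. PNMA2, a neuronal antigen of the Ma family on chromosome 8 from 26365177 to 26366271, had 69 counts with the empty vector and 1 with AP-2α, a ratio of 55.3-fold (9.60 to 2216). Its FPKM values were 2.93 and 0.000588, so the size of its ratio differs between counts and FPKM. IL21R, a cytokine receptor, was 8.95-fold lower (3.90 to 25.3) on 67 and 6 counts. LRRC20 had the most counts of these genes, 939 and 175, and was 4.30-fold lower (3.66 to 5.08). A4GALT, the synthase of globotriaosylceramide, was 3.75-fold lower (2.98 to 4.76), and ATP2A3, a calcium pump of the endoplasmic reticulum, 4.01-fold (2.85 to 5.75). GPC2, a glypican, was 5.81-fold lower (3.16 to 11.7) and TRIM55, a muscle RING finger protein, 6.05-fold (3.21 to 12.6). ZNF467 was 4.43-fold lower (2.82 to 7.23), OLFML2A 4.46-fold (2.85 to 7.29) and SAMD10 8.22-fold (2.98 to 31.6). ODAD1, a component of the ciliary dynein docking complex, had 25 and 1 counts, a log2 ratio of -4.32 (-9.68 to -1.71), and ESPNL had 24 and 1 counts, a ratio of 19.2-fold (3.14 to 791). On the log2(FPKM + 1) scale, which understates low genes, 10 of the 12 highest and 5 of the 12 lowest genes still differed by at least 2-fold.

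**Figure D1:**
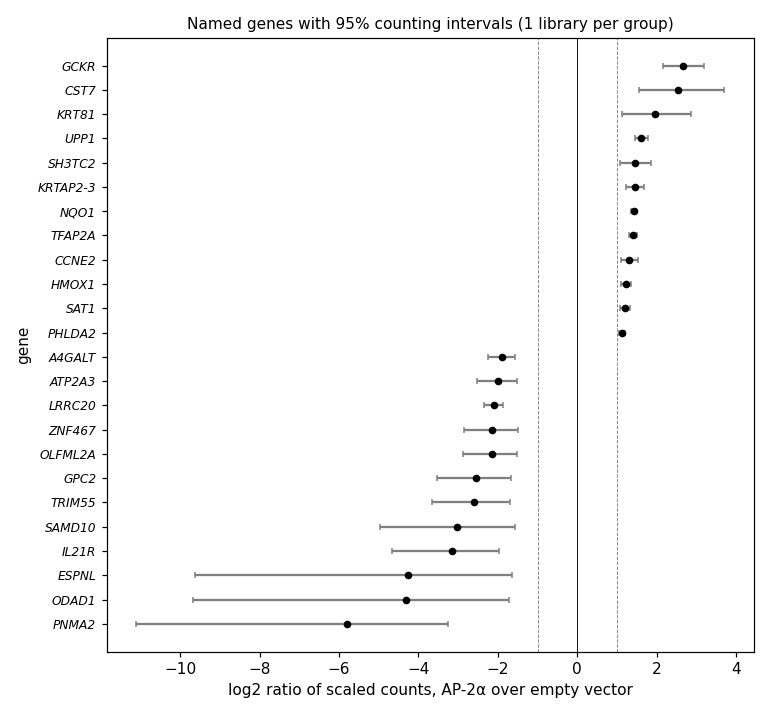
Log2 ratio of scaled counts, AP-2α over empty vector (x axis), for the 12 genes that ranked highest and the 12 that ranked lowest (y axis). Points are the ratio of the 2 libraries, bars the exact 95% counting interval, and dashed lines mark 2-fold; the widest bars belong to PNMA2, ODAD1 and ESPNL, with 1 count each in the AP-2α library.

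Of 12944 measured genes, 85 were called higher and 542 lower with AP-2α, and 7 of the higher and 84 of the lower genes differed by at least 4-fold. The libraries were otherwise similar: 84.1% of measured genes lay within 1.5-fold. Among protein-coding genes 54 were higher and 412 lower, and among the 664 measured new loci 28 were higher and 103 lower. Low-count genes were called more often in both directions, but lower genes outnumbered higher genes at each count level. Of 1054 genes with 20 to 49 counts, 39 were higher and 194 lower. Of 6540 genes with at least 1000 counts, 11 were higher and 41 lower. The levels between were more lopsided, with 16 and 124 from 50 counts, 12 and 119 from 100, and 7 and 64 from 300. There were 6.38 lower genes per higher gene among all measured genes, and 7.47 with a minimum of 100 counts. The log2 ratio also followed sequence properties across genes, with a Spearman rho of -0.27 with GC content and -0.23 with length, where genes are not independent replicates. The higher and lower genes numbered 30 and 224 with a minimum of 100 counts. They numbered 28 and 58 on the log2(FPKM + 1) scale, where no counting interval was applied. After correction for GC content and length they were 50 and 369, over genes with a GC value, of which 56 and 426 were called without correction.

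Genes of the G1/S list stood higher together (list members given below without an interval were not called, and their intervals exclude 1 unless stated). All 29 measured members had a ratio above 1, under each scaling tried, with a median log2 ratio of 0.42 at percentile 100 of random lists, and after correction it stayed at 100. Apart from CCNE2, the 1 member called, the differences were small: PCNA, the sliding clamp of DNA polymerase, was 1.69-fold higher, on 5302 and 7188 counts. Of the 29 measured G2/M genes, 26 had a ratio above 1 (26 to 28 over the scalings tried) and 0 were called. Their median was 0.29, at percentile 99.98 (counting range 99.8 to 100). After correction it lay at 98.83, with a counting range of 93.4 to 99.7 that reached below the limit. NUSAP1, a spindle protein, was 1.57-fold higher and CDK1, the mitotic kinase, 1.47-fold, while the kinetochore proteins CENPF and CENPE had log2 ratios of -0.17 and -0.06, the latter with an interval that held 0.

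Heat shock genes also stood higher, with a median log2 ratio of 0.37 over 15 measured members (percentile 99.96, and 99.98 after correction). HSPA6, an inducible chaperone, was the 1 member called, 3.28-fold higher (1.90 to 5.90) on 19 and 50 counts, and shares sequence with other HSP70 genes. HSPE1, the mitochondrial co-chaperone, was 1.60-fold higher, and DNAJB4 had a log2 ratio of -0.10 with an interval that held 0. Cytosolic ribosomal protein genes lay at percentile 99.95, with 45 of 46 above 1, but after correction for GC content and length they lay at percentile 5.915. RPS24 was 1.35-fold and RPS3A 1.31-fold higher before correction, and RPL3, at a log2 ratio of -0.07, turned positive under the authors' scaling. These genes have many processed pseudogenes, with which reads can be shared. Nuclear genes of oxidative phosphorylation lay at percentile 97.34, and at 10.97 after correction. Among them UQCRQ of complex III was 1.47-fold and NDUFA1 of complex I 1.43-fold higher, while SDHA and COX5B had log2 ratios of -0.13 and -0.06, the latter with an interval that held 0.

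Genes reported as AP-2 targets in the literature stood lower with AP-2α as a list. The list was fixed without an expected direction for its members, so its position does not say whether they followed their reported regulation. Of 29 measured members, 5 were called lower and 0 higher: ERBB3, MMP2, VEGFA, WNT5A and GREB1. ERBB3, a receptor of the EGFR family, was 2.89-fold lower (1.97 to 4.33) on 126 and 35 counts, and the matrix protease MMP2 was 2.41-fold lower (2.13 to 2.74) on 1024 and 340 counts. VEGFA, the angiogenic growth factor, was 2.07-fold lower (1.94 to 2.20), and GREB1 3.71-fold (1.70 to 9.22) on 37 and 8 counts. After correction 4 of the 5 were called, and VEGFA, at 1.93-fold lower (1.81 to 2.06), was not. In the other direction the simple keratin KRT18 was 1.74-fold higher, on 6489 and 9046 counts, and the mitochondrial superoxide dismutase SOD2 1.42-fold. The median log2 ratio was -0.37, at percentile 0.07 with a counting range of 0.02 to 20.3, and at 1.08 after correction with one of 0.356 to 53.6, so at this depth neither position is held over counting error. The list did not stand apart on the log2(FPKM + 1) scale (7.71) or with a minimum of 100 counts (2.585). Of 14 cofactors and regulators of AP-2, CITED4, a transcriptional co-activator, was called lower, 2.85-fold (2.31 to 3.54). CITED2 was 1.47-fold lower and NPM1, a nucleolar protein with many pseudogenes, 1.55-fold higher. That list lay at percentile 24.1, and at 24.7 after correction.

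Mesenchymal and matrix genes stood lower, with 22 of 32 below 1 and a median log2 ratio of -0.37 (percentile 0.12, counting range 0 to 2.29). MMP2, COL5A1 and PDGFRB were called lower: the fibrillar collagen COL5A1 2.28-fold (1.98 to 2.63) and the receptor PDGFRB 2.45-fold (1.91 to 3.19). VIM, the abundant intermediate filament of mesenchymal cells, was 1.28-fold higher, at 2447 and 3140 CPM, and TWIST1 1.59-fold higher. After correction the list lay at percentile 1.14 (counting range 0 to 3.84), COL5A1, with a long GC-rich transcript, was 1.70-fold lower and no longer called, and SNAI2, 1.87-fold lower before, was called at 2.24-fold. On the log2(FPKM + 1) scale the list lay at 2.79. The TGF-beta and BMP list lay at percentile 0.975 (counting range 0.315 to 7.54) with 0 of 23 members called. In it CCN2, a matricellular protein, was 1.74-fold and the BMP antagonist NOG 1.64-fold lower, and SMAD7 was 1.60-fold and ID3 1.33-fold higher. It lay at 14.91 when the mean replaced the median, at 3.81 against random lists not matched, at 3.32 on the log2(FPKM + 1) scale and at 5.22 after correction, and so stood apart under none of these.

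Epithelial markers did not stand apart as lists. In the epithelial adhesion list (18 measured) the claudin CLDN4 and the junction proteins TJP3, F11R and JUP were called lower, by 2.35-fold (1.31 to 4.45), 4.81-fold (1.40 to 25.5), 2.06-fold (1.22 to 3.59) and 2.25-fold (1.25 to 4.27), each with fewer than 100 counts over both libraries. After correction F11R was 1.98-fold lower (1.18 to 3.45) and JUP 1.95-fold (1.08 to 3.69), and neither was called. CLDN7 was 1.41-fold and PKP3 1.19-fold higher, and the list lay at percentile 20.54, or 76.85 after correction. Of 13 measured luminal markers of the urothelium, ERBB3 and the uroplakin UPK1A were called lower, UPK1A by 2.32-fold (1.36 to 4.14) on 55 and 19 counts. The keratins KRT18 and KRT7 were 1.74-fold and 1.71-fold higher, and the list lay at 10.23, or 32.8 after correction. Among 9 measured basal and squamous markers, COL17A1 was 1.46-fold higher, LAMB3 1.22-fold lower and TGM1 1.23-fold lower with an interval that held 1. This list lay at 72.15, or 87.2 after correction.

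Several signalling lists held called members without standing apart. Of 27 Wnt ligands, receptors and targets, 4 were called lower: WNT5A 2.13-fold (1.57 to 2.93), the transcription factor TCF7 2.38-fold (1.85 to 3.08), AXIN2 2.30-fold (1.51 to 3.58) and NOTUM 2.28-fold (1.19 to 4.68). LGR4 was 1.72-fold and WNT7B 1.22-fold higher, and the list lay at percentile 22.84, or 51.6 after correction. Among 9 EGFR ligands and receptors, ERBB3 was called lower, the feedback inhibitor ERRFI1 was 1.71-fold lower, and the ligands EREG and NRG1 were 1.31-fold and 1.14-fold higher. The list lay at 3.91, or 28.4 after correction. Of 25 immediate early and MAPK feedback genes 0 were called, with IER3 1.56-fold and DUSP4 1.34-fold higher, JUN 1.41-fold lower and PHLDA1 at a log2 ratio of -0.58. That list lay at 5.4, or 9.1 after correction. The chemokine CXCL2 was called higher, 2.13-fold (1.61 to 2.83), among 21 NF-kB and cytokine genes, and was 1.74-fold higher and not called after correction. Another chemokine, CCL20, was called lower after correction, 2.38-fold (1.23 to 4.84), and was 1.78-fold lower before it with an interval that held 1. CXCL1 was 1.81-fold higher, IL11 1.74-fold lower and NFKB2 1.39-fold lower, and the list lay at 96.88, or 98.1 after correction (counting range 32.2 to 99.9). Of 28 interferon response genes, ISG15 and IFIT1 were called lower, by 2.03-fold (1.64 to 2.51) and 2.07-fold (1.16 to 3.87). STAT2 was 1.55-fold lower, IFITM3 1.17-fold higher, and the list lay at 20.05, or 9.91 after correction.

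Among metabolic genes, several hypoxia targets were called lower and the cholesterol list stood lower. CA12, a membrane carbonic anhydrase induced by hypoxia, was 2.39-fold lower (2.32 to 2.47), at 846 and 353 CPM, and NDRG1 2.05-fold lower (1.98 to 2.12). With VEGFA these made 3 of 33 hypoxia and glycolysis genes called lower. After correction NDRG1 was 1.98-fold lower (1.91 to 2.05), and neither it nor VEGFA was called, while ANKRD37, 1.93-fold lower before, was called at 2.48-fold (1.83 to 3.41). The glycolytic enzyme LDHA was 1.38-fold higher, at 3029 and 4168 CPM, and BNIP3 1.30-fold. The list lay at percentile 2.975, or 0.52 after correction (counting range 0.26 to 11.02). Of 24 cholesterol biosynthesis genes 0 were called and 17 had a ratio below 1 (15 to 22 over the scalings tried), with a median log2 ratio of -0.15 at percentile 0.64, or 0 after correction; against random lists not matched on expression it lay at 6.59. DHCR7 and LSS, enzymes of the sterol pathway, were 1.48-fold and 1.47-fold lower, SC5D 1.15-fold higher, and IDI1 1.07-fold higher with an interval that held 1. Among 31 genes of the unfolded protein and amino acid stress response, CTH was called lower, 2.18-fold (1.25 to 3.98). The amino acid transporter subunits SLC7A5 and SLC3A2 were 1.66-fold and 1.59-fold higher, DDIT4 1.89-fold and SESN2 1.54-fold lower, and the list lay at 52.6, or 5.55 after correction. Of 23 NRF2-related genes, NQO1 and HMOX1 were called higher and the aldo-keto reductases AKR1C1 and AKR1C3 lower, by 3.44-fold (1.48 to 9.27) and 2.67-fold (1.03 to 8.13), at low counts and with near-identical paralogs. ABCC1 was 1.47-fold lower, and this list lay at 60.16, or 33.8 after correction.

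Of 21 measured p53 targets 0 were called. GADD45A was 1.29-fold and TIGAR 1.34-fold higher, SESN2 1.54-fold and FDXR 1.42-fold lower, and the list lay at percentile 85.4, or 82.4 after correction. Of 26 apoptosis regulators BMF was called lower, 2.16-fold (1.02 to 5.01) on 27 and 10 counts, and after correction it was 1.92-fold lower (0.899 to 4.44) and not called. BIRC2 was 1.40-fold higher, CASP9 1.87-fold and BCL2L1 1.31-fold lower, and the list lay at 75.83, or 40.94 after correction. Of 12 replication-dependent histone genes, which share sequence and yield transcripts that mostly lack poly(A) tails, 0 were called. H2AC6 was 1.63-fold lower (2.02-fold and called after correction), H1-2 had a log2 ratio of -0.58, H1-4 and H4C8 had intervals that held 1, and the list lay at 5.375, or 0.72 after correction (counting range 0.049 to 27.8). Of 8 neural crest and melanocyte markers PMEL was called lower, 3.21-fold (1.03 to 13.2) on 16 and 4 counts. SOX9 was 1.73-fold and SNAI2 1.87-fold lower (SNAI2 2.24-fold and called after correction), MSX1 and MSX2 had intervals that held 1, and the list lay at 13.57, or 22.8 after correction. Of the markers of other cell types, 5 endothelial genes were measured, with ROBO4 1.61-fold higher, ESAM and TEK with intervals that held 1, and the list at 86.74, or 98.4 after correction (counting range 86.7 to 99.9). Only 3 immune cell markers were measured, too few for a percentile; CSF1R and ITGAM were called lower, 3.34-fold (1.34 to 9.96) and 2.29-fold (1.22 to 4.56), with at most 40 counts in a library. The mitochondrially encoded list had 0 measured members.

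**Figure D2:**
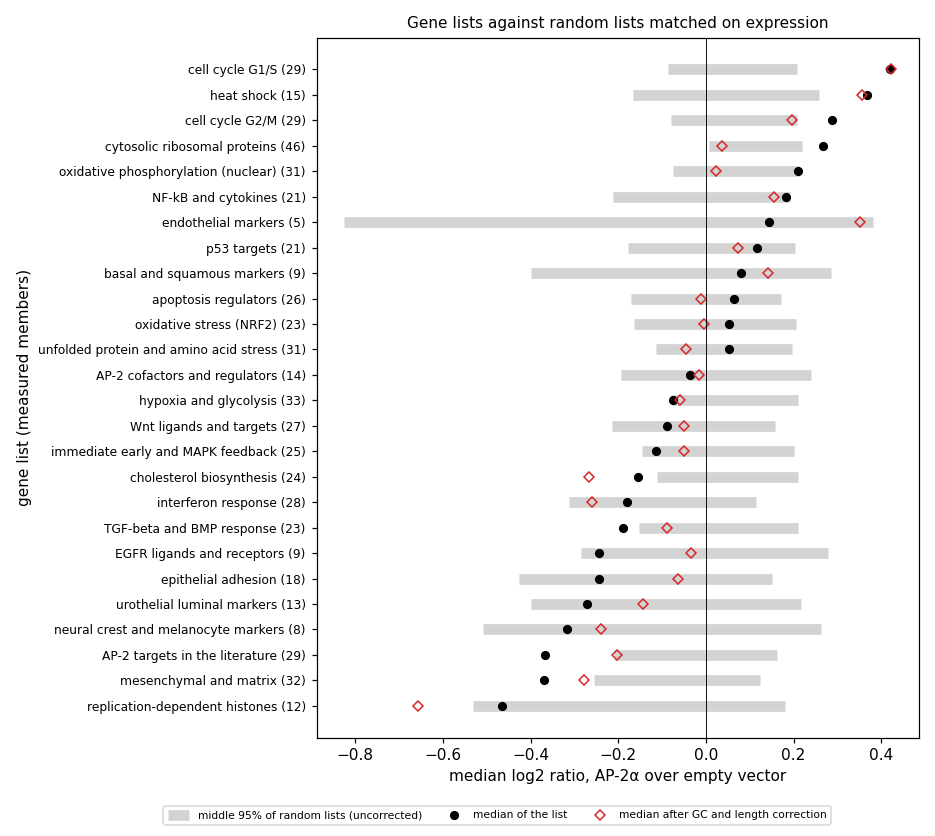
Median log2 ratio, AP-2α over empty vector (x axis), of the 26 gene lists with at least 5 measured members (y axis, number of members in parentheses). Filled circles are the medians, grey bars the middle 95% of 10000 random lists matched on expression, and open diamonds the medians after correction for GC content and length, which have random lists of their own; the G1/S list keeps its median at 0.42, while the ribosomal protein median goes from 0.27 to 0.04.

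Of the 26 lists with a percentile, 4 stood apart on the higher side (G1/S, G2/M, heat shock and ribosomal proteins) and 4 on the lower side (AP-2 targets, mesenchymal and matrix, cholesterol biosynthesis, and TGF-beta and BMP). The counting ranges of the AP-2 target and TGF-beta lists reached past the limit. About 1.3 of 26 lists of independently drawn genes would stand apart by chance. The fixed lists share members, such as ERBB3, and the genes of a list can vary together between cultures. The 1.3 is therefore no measure of how many fixed lists would stand apart without AP-2α. Under the authors' scaling VEGFA, NDRG1, F11R, BMF, ISG15, IFIT1, AKR1C3 and PMEL were no longer called lower.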

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

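The alternatives chosen after seeing the data are the correction for GC content and length, the genes with a GC value, the authors' scaling, protein-coding genes and thinning. Lower genes outnumbered higher genes under every alternative run. Over the planned scalings the higher genes numbered 74 to 86 and the lower 533 to 601. Counts of higher and lower genes moved by over 1.5 times with a minimum of 100 counts (30 and 224) and a fold of at least 1.5 (468 and 1210) or 4 (7 and 84). They also did with an interval bound of at least 2-fold (18 and 94) and FPKM with pseudocount 1 (28 and 58). Stricter or looser rules move them by construction. The FPKM calls use no counting interval, without which the main rule gave 93 and 603. In FPKM with pseudocount 0.1 they numbered 95 and 382, of which 66 and 340 were among the main calls. The move in FPKM was thus larger with the larger pseudocount. Higher genes alone moved with restriction to genes that have a GC value (56, uncorrected) and to protein-coding genes (54), by leaving out loci; the correction, run on the former, took 56 to 50, of which 38 were among the 85. The log2 ratio of TFAP2A was 1.37 to 1.48 over the scalings and 1.43 after correction, but 1.91 and 1.95 in FPKM with pseudocounts 1 and 0.1. None of the called named genes reversed; of the 117 named genes besides TFAP2A, called ones included, 49 moved beyond their counting interval in FPKM with pseudocount 1, 48 after correction and 13 under total-count scaling. Of 155 list positions under alternatives, 130 stayed on the same side of the limits, and the cause of a crossing was not tested unless stated. After correction for GC content and length, ribosomal proteins went from the higher to the lower side of random lists (5.915) and no longer stood apart. Their median log2 ratio stayed above 0, at 0.04, with 28 of 46 members above 1. TGF-beta and BMP no longer stood apart after it (5.22). Also after correction, NF-kB (98.1), endothelial markers (98.355), hypoxia (0.52) and histones (0.72) crossed a limit. Each had a counting range that reached back across it (32.2 to 99.9, 86.7 to 99.9, 0.26 to 11.02 and 0.049 to 27.8). Without crossing a limit, epithelial adhesion (76.85), G2/M (98.83), Wnt (51.62), EGFR (28.365), unfolded protein stress (5.55), cholesterol (0) and oxidative phosphorylation (10.97) moved beyond their counting range. In FPKM, AP-2 targets (7.71), mesenchymal and matrix (2.79) and TGF-beta (3.32) no longer stood apart, NF-kB (99.33) and EGFR (2.12) did, and cholesterol moved (0.07). With a minimum of 100 counts, AP-2 targets (2.585) no longer stood apart, EGFR (2.14), hypoxia (1.95) and histones (1.615) did, and luminal markers (94.44) and TGF-beta (0.11) moved. With the mean of members, TGF-beta (14.91) no longer stood apart, NF-kB (97.87), hypoxia (0.03) and oxidative phosphorylation (99.83) did, and immediate early genes (21.95), cholesterol (0.13) and ribosomal proteins (100) moved. With random lists not matched, TGF-beta (3.81) and cholesterol (6.59) no longer stood apart, epithelial adhesion (2.17), oxidative phosphorylation (99.595) and histones (0.27) did, and AP-2 targets (0.01), interferon (2.68), hypoxia (19.225) and ribosomal proteins (100) moved. With listed genes kept out of the random lists, oxidative phosphorylation stood apart (98.37). Too few members with 100 counts remained for a position of the endothelial list. Depth limits the low genes: a gene at the minimum of 20 counts needs more than a 2-fold ratio for its interval to exclude 1.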

Other observations

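The 6 gene lists of the next paragraph, the loci after it, both TFAP2A tests and the calculation of background level were chosen after the values of single genes had been seen, and the correction for GC content and length was also added then. The counting ranges of those lists, and the lists without members that are not subunits, were added after the positions had been seen. The outcomes of the remaining tests had not been seen when the tests were written, though the trends with GC content and length had. Every hypothesis was formed and tested on the same 2 libraries.

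Genes of the circadian clock output lay low with AP-2α as a list. All 17 measured members had a ratio below 1 (15 under the authors' scaling, where CRY1 and NR1D2 turned above 1), with a median log2 ratio of -0.60, but the intervals of 6 held 1 and only 3 met the 2-fold rule, the transcription factors DBP (2.02-fold, 1.66 to 2.47), TEF (2.06-fold, 1.63 to 2.63) and KLF9 (2.05-fold, 1.62 to 2.60). After correction TEF was 1.81-fold lower (1.43 to 2.31) and KLF9 1.98-fold (1.57 to 2.51), so that DBP alone still met it, and under the authors' scaling none of the 3 did. PER1, a core clock gene, was 1.65-fold lower on 940 and 457 counts and BHLHE41 1.96-fold, while CRY1 was 1.01-fold and NR1D2 1.04-fold lower with intervals that held 1. The hypothesis that a list moves together beyond GC content, length and abundance was tested for 6 lists by the percentile after correction and its counting range. Clock output, with 16 of 17 members below 1 and a median of -0.49 after correction, lay at 0.01 (0 to 0.695). Mitochondrial ribosomal protein genes (68 measured) had 66 members above 1 (64 to 67 over the scalings) and a median of 0.33 before correction, and 55 above 1 and a median of 0.18 after it, where they lay at 99.99 (99.6 to 100). Genes with the symbol stems of proteasome subunits lay at 99.98 before correction and at 85.0 after it (47.6 to 90.4), and those with the stems of ion channel subunits at 34.5 after it (10.5 to 92.9). Without the 1 and 8 members that are not such subunits these lists lay at 77.4 (41.8 to 87.6) and 21.5 (4.77 to 85.0), so neither stood apart after correction; 10 of the 68 channel subunits left were called lower, and 8 of these also after correction. The aryl hydrocarbon receptor battery, with NQO1 and CYP1A1 called higher, lay at 91.6 before correction and at 98.08 after it (85.8 to 99.95), so the sequence trend does not give its position, and whether the list stands apart is not settled at this depth. Of laminins and type IV collagens, LAMA5 and COL4A2 were called lower and 1 member higher. That list lay at 0.03 before correction and at 2.43 after it (0.189 to 17.1). Here a sequence trend and a difference of its own cannot be told apart at this depth. After correction LAMA5 was 1.38-fold (1.31 to 1.45) and COL4A2 1.66-fold lower (1.54 to 1.79), and neither was called. The member called higher was still called. The correction left the clock and mitochondrial ribosome lists beyond the limits, which argues against the sequence trend as the whole cause of their positions. Both lists were chosen after gene values had been seen, however, so their positions do not show that the members move together, and that choice, culture density, time of harvest and AP-2α all stay open.

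Some loci without a gene symbol had large ratios at low counts. The new locus on chromosome 14 from 101156172 to 101159671 (GRCh37) had 1 count with the empty vector and 43 with AP-2α, a ratio of 53.6-fold (9.13 to 2167), and a locus on chromosome 20 from 57206077 to 57210790 had 1 and 37, a ratio of 46.2-fold (7.79 to 1872). On the lower side a locus on chromosome 4 from 26859266 to 26860786 had 38 and 1, a ratio of 30.5-fold (5.15 to 1234). The most abundant called locus without a symbol, on chromosome 1 from 564460 to 570305, had 9750 and 22768 counts and was 2.91-fold higher (2.84 to 2.98). That region holds a known nuclear copy of mitochondrial DNA, and whether its reads came from mitochondrial transcripts was not tested.

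More genes were called lower than higher, 542 against 85. Thinning the empty-vector library left 6.10 lower genes for each higher gene, which argues against the lower depth of the AP-2α library as the cause. The genes measured before thinning were kept, so an effect of depth through the count minimum is not covered. A trend with GC content and length is not the whole cause, since there were still 7.38 after its correction. Background reads in the empty-vector library were checked on 331 olfactory receptor genes, whose pooled log2 ratio was -0.44 (-1.20 to 0.29) on only 70 counts; an interval that held 0 had been set beforehand as evidence against an excess, but it also holds the -0.34 of the genes with 20 to 49 counts, so it excludes nothing. At most 0.169 background counts per kilobase were compatible with those genes, however, whereas the lower genes had a median excess of 34.8 counts, and for 0% of the 542 was the excess within 2 times that background. That calculation takes background as even over the genome, so it covers only such background. Genes with few counts also lay lower as a whole, with a median log2 ratio of -0.37 at 20 to 49 counts against 0.06 from 1000. What share of the lower genes goes with that shift was not tested. Background that differs between loci, an effect of AP-2α, a difference between cultures and a difference in RNA handling remain open. No replicate separates them.

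The positions of 3 lists were set against the trend with GC content and length. The G1/S list lay at percentile 100 both before and after correction, counting range 100 to 100, which argues against that trend as the cause. The mesenchymal and matrix list lay at 1.14 after correction with a counting range of 0 to 3.84, so here the trend and a difference of its own cannot be told apart at this depth. The ribosomal protein list went from 99.95 to 5.915, so its higher position may come from the short transcripts of these genes (median length 980.5 bases). A difference in growth between the cultures could raise the G1/S genes with or without AP-2α, and was not tested.

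The TFAP2A ratio was larger in FPKM than in counts, by 0.54 on the log2 scale. Library scaling would give other genes the same gap, but over 6540 genes with at least 1000 counts the median gap was 0.0495. The TFAP2A gap lay at percentile 99.9 of those genes. Expressed as a length, by normalized score over FPKM set to the median gene, the same gap is 3014 bases with the empty vector and 2152 with AP-2α. Reads assigned to shorter TFAP2A transcripts in the AP-2α library, as from a cDNA without the native untranslated regions, are a candidate explanation that these values do not test, since they restate the gap; it needs the vector sequence and the reads.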
